A study of Homo sapiens with 9 samples.

How the data were processed

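Chromatin immunoprecipitation sequencing (ChIP-seq) was performed on 786-O, an established human clear cell renal carcinoma cell line. The series analysed here has 9 libraries, 1 per condition, of which 4 are sonicated input chromatin. The other 5 are immunoprecipitates: p65, the RELA subunit of NF-κB, in control, siTEAD4, vehicle and XMU-MP-1 cells, and TEAD, the DNA-binding partner family of YAP, in XMU-MP-1 cells. XMU-MP-1 is an inhibitor of the Hippo kinases MST1 and MST2, which act upstream of YAP. The labels do not say which TEAD protein the antibody recognises. The name siTEAD4 is from the sample title, and the treatment label of the same sample reads siTEAD. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, and libraries were size selected between 300 and 700 bp.

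Per the submitters' processing notes, the tools were fastp, Bowtie2 2.4.5 and MACS2, with the hg19 genome build. The MACS2 version and settings, and which input served as the control of which list, are not given in the sources used here. Each of the 5 immunoprecipitates has 1 list of peaks in narrowPeak format, called by the authors on that library alone. Peak numbers skip 14 values in the control list, 18 in the list labelled siTEAD4, 147 in the vehicle list, 7 in the XMU-MP-1 list and 96 in the TEAD list, so at least that many called peaks were taken out before deposit. For each peak the authors deposited a fold enrichment of the summit over the local background, a −log10 p-value and a −log10 q-value. They also deposited a whole-number score, within 1 of 10 times the −log10 q-value, which was not used. The position of the summit, in bp from the peak start, is in the deposited lists as well. The lowest −log10 q in the lists lies between 1.30 and 1.55, which places the calling threshold near a q of 0.05. These folds and q-values are the authors' own values per peak. They were used to rank or filter peaks within a list. Folds of different lists are set side by side only as list medians and for single regions. Each is relative to the background of its own library, so they show no change between lists.

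The peak identifiers in the list of the sample labelled siTEAD4 carry the name p65_Vert, which appears in no label used here. The identifiers of the other 4 lists carry the names of their labels. The list is called "labelled siTEAD4" throughout.

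Peaks were compared by position. A peak was called kept when at least 1 bp of it lay in a peak of the treated list, and lost otherwise. Both words describe lists of called peaks. Shares of peaks are given with 95% Wilson intervals, and differences of shares with 95% normal-approximation intervals. Both cover the counting of peaks only and treat peaks as independent. There is 1 library per condition, so no difference between conditions has a replicate check, and no p-value is given. Chance overlap was estimated by moving all peaks of a chromosome by 1 random offset, wrapped at the last position that any list reaches, in 1000 draws (100 where the TEAD list was moved). A second estimate moved every peak by 10 kb in either direction, which keeps the regional density of peaks. Differences in the share kept between peaks with and without a TEAD peak were also standardised to the same deciles of fold, or to 20 classes of strength read in both reference lists. Whether sites with a TEAD peak were stronger than measured was read from the control and vehicle lists: the normal score of −log10 q in one list was regressed on that in the other and on the TEAD peak. The result was set against the difference in strength that a probit model of kept peaks would need, with intervals from 500 bootstrap draws of peaks. This takes the errors of both lists as independent, and was chosen after seeing the data. Overlaps were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and with bedtools 2.31.1 for the overlap of 50% of the shorter peak. The code was tested on simulated data with known overlaps, pileups and differences.

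The lists give no read totals. The fold and p-value of a MACS2 peak follow from the pileup of fragments at the summit and the local background: the fold is the pileup plus 1 over the background plus 1, and p is the Poisson tail of the pileup. These 2 equations were solved for each peak. In 3 lists the pileups were whole numbers. In the control and XMU-MP-1 lists they were multiples of 0.587 and 0.783, as when an immunoprecipitate is scaled down to a smaller input. Between 99.96% and 100% of the peaks of a list were solved to within 0.005 of their −log10 p. The 1st percentile of the local background was taken as its genome-wide floor. Divided by the shortest peak (176 to 214 bp, which MACS2 by default sets to the fragment length), it gives a relative depth on which the peaks were called. Pileups at the summits of overlapping peaks, divided by the scale of their list, were compared between lists to within 10% of their median ratio. The ratio of the depths before the scaling of the immunoprecipitates was also computed. These readings rest on the default settings of MACS2.

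Before the data were examined, the comparisons, alternatives and the rule for named regions were fixed. For each treatment the rule takes the 10 strongest lost peaks, the 10 strongest kept peaks and the 5 strongest peaks found only after treatment. For TEAD it takes the 10 strongest peaks. Strength is the fold, and only chromosomes 1 to 22 and X were used. The fixed rule also named genes near peaks, and 9 gene lists, the position of peaks in genes and motif counts were planned. These 3 parts of the design were not run, because no annotation or sequence of hg19 was used here and coordinates of another build cannot be joined to these peaks. Regions are therefore named by position only. Coordinates are 1-based, hg19. Alternatives were a −log10 q of at least 5 or 10, a fold of at least 5, overlap of 50% of the shorter peak, summits within 200 bp, only the strongest reference peaks, and equal deciles of fold. A −log10 p of at least 6, classes by −log10 q or in both reference lists, the moves by 10 kb and the settings for sites kept in both treated lists were chosen after seeing the data.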

Results

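Binding of p65 in 786-O cells was profiled by ChIP-seq in 2 pairs of libraries: control against siTEAD4, and vehicle against XMU-MP-1. TEAD was profiled in XMU-MP-1 treated cells. The control list held 15465 p65 peaks, the vehicle list 17958, the list labelled siTEAD4 1813 and the XMU-MP-1 list 1649. The TEAD list held 23460 peaks. Median peak length was 301 bp in the control, 297 bp in the vehicle, 281 bp in the siTEAD4-labelled, 334 bp in the XMU-MP-1 and 350 bp in the TEAD list. Median fold enrichment, each over the background of its own library, was 5.98, 5.87, 5.37, 5.96 and 6.27 in the same order. The lists give no read totals. The depth implied by the background of the peaks was 1.81 times that of the control for the list labelled siTEAD4, and 1.25 times that of the vehicle for the XMU-MP-1 list. Before the scaling of the immunoprecipitates these ratios were 1.06 and 1.597. For TEAD it was 0.780 times that of the vehicle p65 library.

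The control and vehicle libraries, the references of the comparisons, show how far 2 p65 lists from cells with neither siTEAD4 nor XMU-MP-1 coincided. Of the control peaks, 12297 (79.5%, 95% interval 78.9 to 80.1) had a vehicle peak, and 12303 vehicle peaks (68.5%, 67.8 to 69.2) had a control peak. Random placement gave 0.440% of control peaks on average and at most 0.634% in 1000 draws. Summits of overlapping peaks lay 31 bp apart at the median. The coincidence depended on strength: all 1546 control peaks in the strongest decile of fold had a vehicle peak, against 64.8% (62.4 to 67.2) in the weakest decile. The strongest site of the control list, chromosome 13 from 110317996 to 110318683, had a fold of 51.5 there and 55.6 in the vehicle list.

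There is 1 library per condition, so differences between lists have no replicate check. The first comparison asks how p65 occupancy differs under an siRNA against TEAD, named siTEAD4 in the sample title and siTEAD in its treatment label. The list labelled siTEAD4 held 1813 p65 peaks, and the control list 8.53 times as many. Of the control peaks, 1737 (11.2%, 10.7 to 11.7) were kept and 13728 were lost. Most peaks of the list labelled siTEAD4 were control sites: 1746 of 1813 (96.3%, 95.3 to 97.1) had a control peak. A vehicle peak was found at 1766 of them (97.4%, 96.6 to 98.0), so the overlap does not single out the control as its reference. The peak identifiers of this list carry the condition name p65_Vert. The treatment behind it, and its pairing with the control list, therefore rest on the sample label alone.

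Kept control peaks were the stronger and longer ones, with a median fold of 12.7 (interquartile range 8.56 to 17.6) and a median length of 500 bp. Lost peaks had a median fold of 5.72 (4.66 to 7.42) and a median length of 287 bp. In the strongest decile of the control list 57.5% (55.0 to 59.9) were kept, in the next decile 22.1% (20.1 to 24.2), and in the weakest decile 2.39% (1.74 to 3.28). The share kept ranged from 8.65% on chromosome 18 to 13.7% on chromosome 11. Among as many of the strongest control peaks as the list labelled siTEAD4 holds, 53.6% were kept.

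Strong control sites were found on both sides of this division. The strongest lost site lay on chromosome 11 from 109957601 to 109958137, with a control fold of 32.96. It had a vehicle fold of 38.6 and no peak in either treated list or in the TEAD list. Next came chromosome 19 from 45504318 to 45504885 (fold 28.5), chromosome 6 from 18501838 to 18502451 (28.5) and chromosome 17 from 7747106 to 7747653 (27.0). Like all 1546 control peaks of the strongest decile, the 10 strongest lost sites, with control folds of 22.9 to 32.96, were also vehicle peaks. Only 1 of them, the site on chromosome 19 just named, had an XMU-MP-1 peak, with a fold of 6.45. TEAD was called at 1 of the 10, the site on chromosome 17, with a fold of 4.48.

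All 10 of the strongest kept sites, with control folds of 36.3 to 51.5, had peaks in the vehicle and XMU-MP-1 lists as well, and 7 had a TEAD peak. On chromosome 10 a region of 1983 bp from 104153691 to 104155673 had a control fold of 44.1 and a siTEAD4-labelled fold of 23.3. On chromosome 14 a region from 94811669 to 94813247 had folds of 39.2 and 17.4 in the same lists. On chromosome 22 the site from 38614419 to 38615102 had folds of 39.1 and 10.5, beside a TEAD fold of 18.1. The site on chromosome 11 from 115795474 to 115796663 had a control fold of 40.4 and a siTEAD4-labelled fold of 13.1, beside a TEAD fold of 12.3.

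Only 67 peaks labelled siTEAD4 (3.70%) had no control peak, and 33 of them were vehicle peaks. No other p65 list held 28 of the 67. The strongest of the 67, on chromosome 5 from 180648670 to 180649462, had a fold of 10.9. It was also a vehicle peak (fold 4.60), an XMU-MP-1 peak (10.0) and a TEAD peak (27.5).

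**Figure D1:**
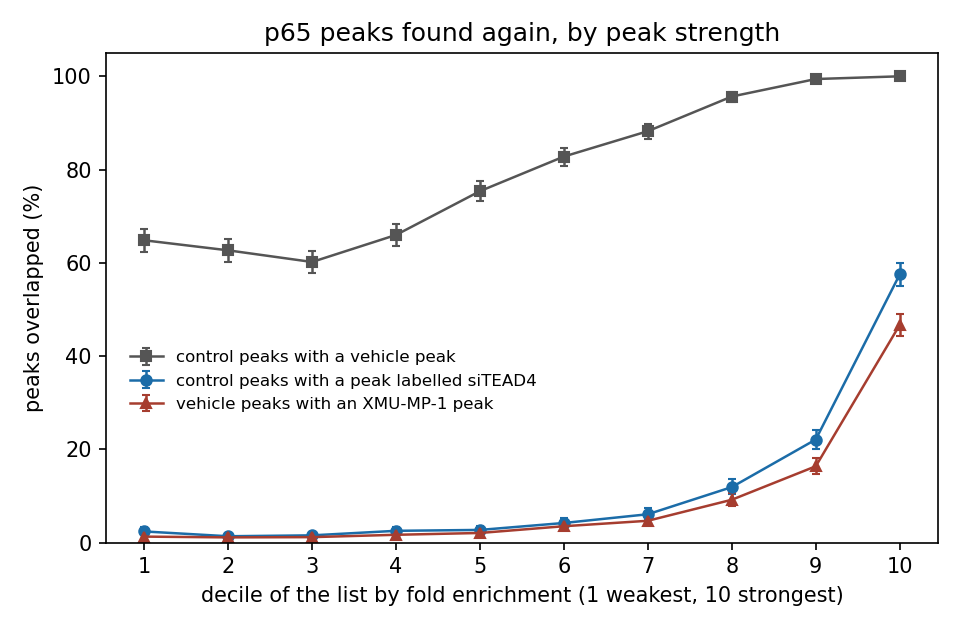
Share of p65 peaks overlapped by another p65 list (vertical axis, percent) in each decile of the list by fold enrichment (horizontal axis, 1 weakest to 10 strongest); bars are 95% Wilson intervals over peaks. The share of control peaks with a vehicle peak reaches 100% in the strongest decile, where 57.5% had a peak labelled siTEAD4 and 46.7% of vehicle peaks had an XMU-MP-1 peak.

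The second comparison asks how p65 occupancy differs when the Hippo kinases MST1 and MST2 are inhibited by XMU-MP-1. The XMU-MP-1 list held 1649 p65 peaks, and the vehicle list 10.9 times as many. Of the vehicle peaks, 1575 (8.77%, 8.37 to 9.19) were kept and 16383 were lost. Of the XMU-MP-1 peaks, 1578 (95.7%, 94.6 to 96.6) were vehicle sites.

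Kept vehicle peaks had a median fold of 12.9 (8.70 to 18.7) and a median length of 528 bp, and lost ones 5.73 (4.65 to 7.52) and 284 bp. The strongest decile of the vehicle list kept 46.7% (44.4 to 49.0) of its peaks, and the weakest 1.28% (0.855 to 1.91). The share kept ranged from 6.32% on chromosome 16 to 10.9% on chromosome 7. Among as many of the strongest vehicle peaks as the XMU-MP-1 list holds, 48.5% were kept.

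The strongest lost vehicle site was on chromosome 17 from 73873011 to 73873647, with a vehicle fold of 41.9 and a control fold of 29.4. The site on chromosome 11 that led the control peaks lost from the list labelled siTEAD4 was the next, with a vehicle fold of 38.6. It was followed by chromosome 1 from 200122310 to 200122912 (34.6) and chromosome 7 from 44790389 to 44791105 (33.9). Like all 1795 vehicle peaks of the strongest decile, the 10 strongest lost vehicle sites, with folds of 27.2 to 41.9, were also control peaks. Of these, 8 also had a peak labelled siTEAD4, and 4 had a TEAD peak.

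On the other side, the strongest kept vehicle site, on chromosome 1 from 232980399 to 232981092, had a vehicle fold of 63.9 and an XMU-MP-1 fold of 30.6. The highest fold of both treated lists was at 1 site, on chromosome 14 from 35872782 to 35873595. It had an XMU-MP-1 fold of 38.2, a siTEAD4-labelled fold of 34.2, a vehicle fold of 44.3, a control fold of 35.5 and a TEAD fold of 11.7. On chromosome 10 the site from 99642112 to 99642788 had a vehicle fold of 51.6, an XMU-MP-1 fold of 30.1 and a TEAD fold of 24.1. All 10 of the strongest kept vehicle sites had control and siTEAD4-labelled peaks, and 7 had a TEAD peak.

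Of the XMU-MP-1 peaks, 71 (4.31%) had no vehicle peak. Of these 71, 25 were control peaks, 14 had a peak labelled siTEAD4 and 40 were in no other p65 list. Their median fold was 5.15, against 5.96 in the whole list. The 5 strongest had folds of 10.6 to 32.99, and no other p65 list held any of them. The first was on chromosome 6 from 25129494 to 25130017 (fold 32.99), the next on chromosome 4 from 183745810 to 183746213 (20.3) and the third on chromosome 1 from 96407189 to 96407586 (17.0). TEAD was called at 1 of the 5, on chromosome 15 from 88817853 to 88818264, with a fold of 4.81.

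Both treated lists were then compared over the 12297 control peaks that were also vehicle peaks. Of these, 1175 (9.56%, 9.05 to 10.1) were kept in both treated lists, 548 only in the list labelled siTEAD4, 371 only in the XMU-MP-1 list, and 10203 (83.0%, 82.3 to 83.6) in neither. Independent lists would share 217 of these peaks. The number expected from the shares kept within 20 classes of strength was 580 with classes by control fold, and 701 with classes by −log10 q read in both reference lists. An XMU-MP-1 peak was found at 68.2% (66.0 to 70.4) of the sites kept in the list labelled siTEAD4, and at 3.51% (3.17 to 3.88) of the sites lost there. Sites kept in both had a median control fold of 13.8, those kept only in the list labelled siTEAD4 10.6, those kept only in the XMU-MP-1 list 8.05, and those kept in neither 6.13. A TEAD peak lay at 76.9% (74.4 to 79.2) of the sites kept in both, at 64.2% (60.1 to 68.1) of those kept only in the list labelled siTEAD4 and at 79.5% (75.1 to 83.3) of those kept only in the XMU-MP-1 list. At sites kept in neither this share was 45.0% (44.03 to 46.0).

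The third question is how p65 and TEAD sites coincide. In XMU-MP-1 cells 1240 of the 1649 p65 peaks (75.2%, 73.1 to 77.2) had a TEAD peak. The same TEAD list covered 71.6% (69.5 to 73.6) of the peaks labelled siTEAD4, 47.4% (46.6 to 48.2) of the control peaks and 45.6% (44.9 to 46.4) of the vehicle peaks. Moving the p65 peaks by 10 kb left 4.12% of XMU-MP-1 peaks and 2.37% of vehicle peaks with a TEAD peak. Random placement gave at most 1.33% and 0.824%. Summits of p65 and TEAD lay 56.5 bp apart at the median in XMU-MP-1 cells, and 46.5% of these pairs were within 50 bp. Between the control and vehicle p65 lists 70.0% of pairs were within 50 bp.

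**Figure D2:**
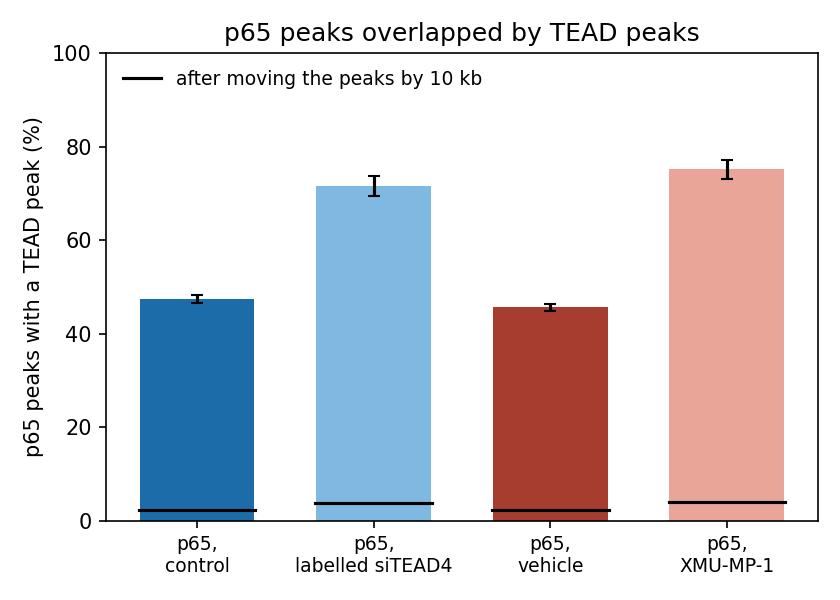
Share of the p65 peaks of each list that overlap a TEAD peak of XMU-MP-1 cells (bars, percent; error bars are 95% Wilson intervals over peaks), with the share after moving the p65 peaks by 10 kb (black lines). Both treated lists lie above 70%, and the control and vehicle lists at 47.4% and 45.6%.

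Most TEAD sites had no p65 peak. Of the 23460 TEAD peaks, 34.5% (33.9 to 35.1) had a vehicle p65 peak and 5.26% (4.98 to 5.55) an XMU-MP-1 p65 peak. In the strongest decile of the TEAD list these shares were 52.6% (50.5 to 54.6) and 15.4% (14.0 to 16.9), and in the weakest 27.4% (25.6 to 29.2) and 2.56% (1.99 to 3.28). The strongest TEAD site was on chromosome 1 from 246598686 to 246599443, with a fold of 79.6 and no p65 peak in any list. The next, on chromosome 19 from 2540466 to 2541350 (77.1), had p65 folds of 5.36 in the control and 10.0 in the vehicle list and none in the treated lists. The third, on chromosome 15 from 63399902 to 63400832 (75.2), had p65 peaks in all 4 lists, with folds of 23.04 in the control, 24.9 in the vehicle, 7.40 in the siTEAD4-labelled and 13.6 in the XMU-MP-1 list. Of the 10 strongest TEAD sites, 7 had control and vehicle p65 peaks and 5 had a p65 peak in each treated list.

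Control p65 peaks with a TEAD peak were kept in the list labelled siTEAD4 more often than those without. The shares were 17.3% (16.4 to 18.2) of 7330 peaks and 5.79% (5.30 to 6.32) of 8135 peaks, a difference of 11.5 percentage points (10.5 to 12.5). The median control fold was 5.96 with and 6.01 without a TEAD peak. For vehicle peaks the median vehicle fold was 5.99 with and 5.78 without. In the XMU-MP-1 list 14.9% (14.2 to 15.7) of 8193 vehicle peaks with a TEAD peak and 3.61% (3.26 to 4.004) of 9765 without were kept, a difference of 11.3 points (10.4 to 12.2). At equal deciles of fold the differences were 10.6 points (9.77 to 11.5) and 10.1 points (9.36 to 10.8). The shares kept were then 16.8% with and 6.15% without a TEAD peak in the list labelled siTEAD4. In the XMU-MP-1 list they were 14.0% and 3.95%. Among peaks of both reference lists, in the strongest of 20 classes of −log10 q read in both, 93.6% (90.8 to 95.6) of control peaks with and 79.6% (73.6 to 84.5) of those without a TEAD peak were kept. For vehicle peaks these shares were 87.0% (83.4 to 89.95) and 61.7% (54.9 to 68.0). A difference was also present between the reference lists. At equal fold, 83.9% of control peaks with and 75.6% of those without a TEAD peak had a vehicle peak. This is a difference of 8.28 points (7.11 to 9.44), at shares far above those kept in the treated lists. Relative to these shares it is smaller than the differences in the treated lists.

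**Figure D3:**
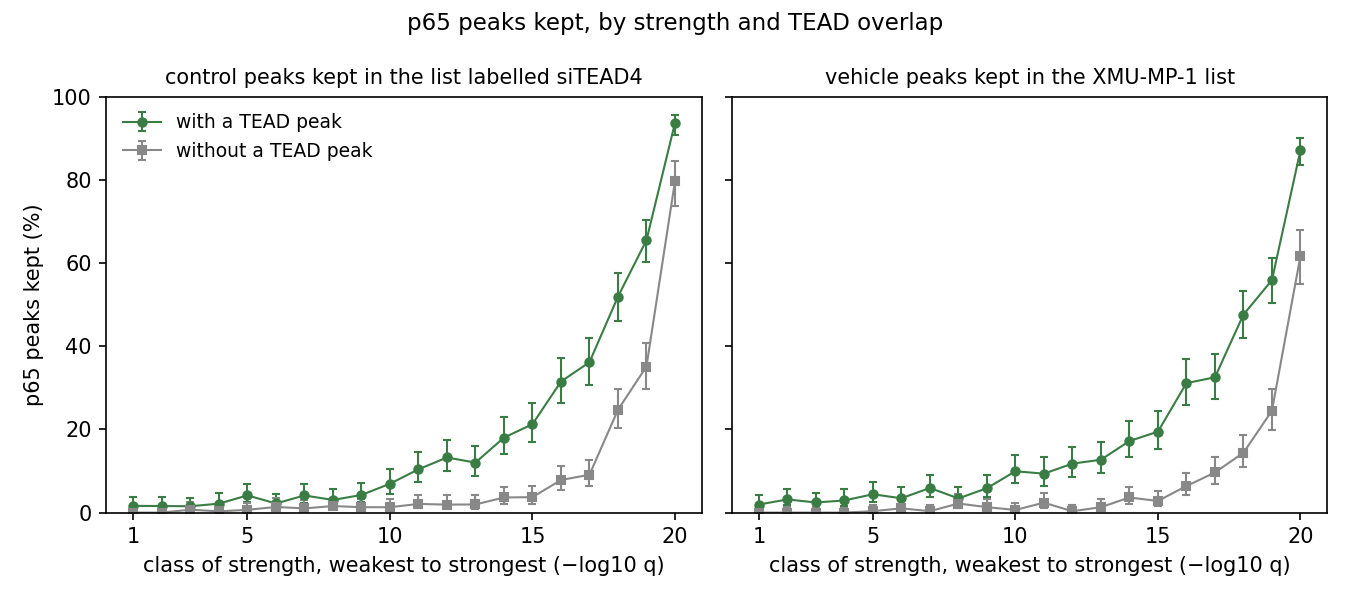
Share of p65 peaks kept after treatment (vertical axis, percent) among peaks found in both the control and vehicle lists, in 20 classes of strength by −log10 q read in both lists (horizontal axis), with (green circles) and without (grey squares) a TEAD peak; bars are 95% Wilson intervals. In the strongest class 93.6% against 79.6% were kept in the list labelled siTEAD4 (left), and 87.0% against 61.7% in the XMU-MP-1 list (right).

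A region chosen after its values were seen gives an example. When TEAD peaks up to 12.5 kb apart were joined, the region with the most peaks lay on chromosome 8 from 128863806 to 128944434, a span of 80.6 kb. It held 19 TEAD peaks, the strongest with a fold of 21.6. The same span held 14 control and 12 vehicle p65 peaks, 3 peaks labelled siTEAD4 and 2 XMU-MP-1 peaks. The site with the highest control and vehicle p65 fold there, 11.1 and 11.2, was called in all 5 lists, with a siTEAD4-labelled fold of 4.29, an XMU-MP-1 fold of 7.03 and a TEAD fold of 13.6.

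**Figure D4:**
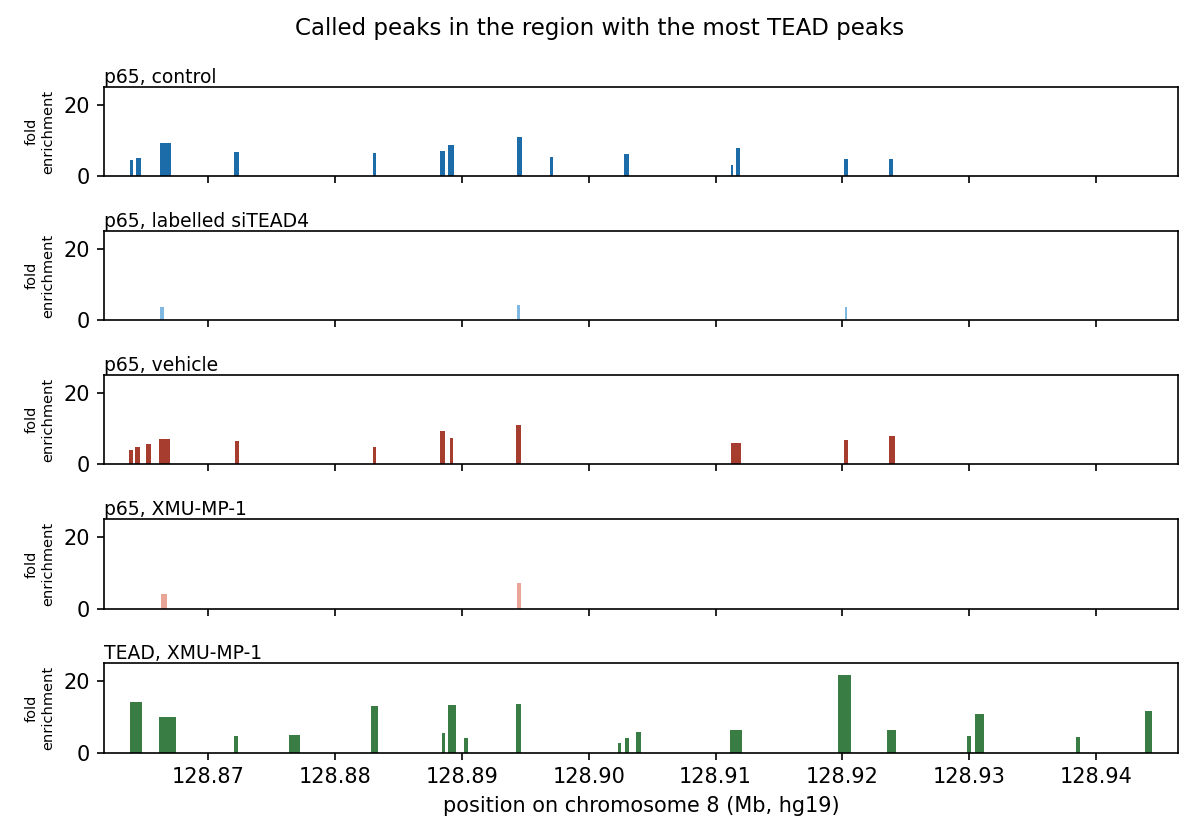
Called peaks on chromosome 8 (horizontal axis, position in Mb, hg19) in the region with the most TEAD peaks, drawn to scale with the authors' fold enrichment as height (vertical axis, the same range in each row). The rows show 14 control, 3 siTEAD4-labelled, 12 vehicle and 2 XMU-MP-1 p65 peaks above 19 TEAD peaks.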

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

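Chosen after seeing the data were the −log10 p limit, the classes by −log10 q or in both reference lists, and each setting for sites kept in both treated lists. Of 45 recomputed values, 18 stayed within the 95% interval of the reported value (for ratios of peak numbers, within 1.5 times), and 27 moved beyond it. None reversed, but only the ratios and differences could, because a share of peaks has no direction. The share of control peaks kept in the list labelled siTEAD4 was 11.96% at a −log10 q of at least 5, 12.7% at 10, 9.50% at a fold of at least 5 and 11.86% at a −log10 p of at least 6. For vehicle peaks in the XMU-MP-1 list it was 9.90% and 10.3% at the q limits and 9.25% at the p limit. With only the strongest reference peaks, as many as the treated list holds, these shares were 53.6% and 48.5%; this setting drops the weaker peaks, which were kept least often. The share of control peaks with a vehicle peak was 78.5% and 80.9% at the q limits, 78.8% with 50% of the shorter peak covered and 77.5% with summits within 200 bp. The share of XMU-MP-1 p65 peaks with a TEAD peak was 68.6% and 57.9% at the q limits and 66.1% with summits within 200 bp. The q limits also cut the TEAD list, to 17877 and 10576 peaks. Against the whole TEAD list, the lowest share in any decile of p65 fold was 67.3%, and the strongest decile had 80.5%. Stronger p65 peaks thus did not have a TEAD peak less often. The difference in the share kept with and without a TEAD peak, in percentage points, was 13.8 for the list labelled siTEAD4 and 14.0 for XMU-MP-1 with TEAD peaks of a −log10 q of at least 10, and 9.27 and 9.72 with summits within 200 bp. At equal deciles of −log10 q it was 9.22 and 9.17, and at equal deciles of fold 10.1 for XMU-MP-1. Among peaks of both reference lists it was 10.4 for the list labelled siTEAD4 by −log10 q and 13.3 for XMU-MP-1 by fold. Of the sites common to control and vehicle, 10.4% were kept in both treated lists at a −log10 q of at least 5, and 12.6% were kept in the XMU-MP-1 list when the list labelled siTEAD4 was left out, which removes a condition. For the other moves the cause was not tested. Alternatives for gene lists, gene positions and motifs were not run. No paired analysis was possible because each condition has 1 library.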

Other observations

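Tests chosen only after the result was seen were those of depth for the list labelled siTEAD4, of a common reduction by unmeasured strength, of local background, of strength for sites kept in both treated lists, and of a library deposited under both labels; the joined TEAD regions and the regions named here were also chosen after their values were seen. Of 11370 TEAD peaks with no other within 12.5 kb, 28.9% had a vehicle p65 peak and 3.35% an XMU-MP-1 p65 peak. Of 336 clusters of 5 or more TEAD peaks, 92.3% held a vehicle and 42.6% an XMU-MP-1 p65 peak. A p65 peak anywhere in the span of a cluster was counted, and these 336 clusters held 2158 TEAD peaks. Larger shares than at single TEAD peaks therefore follow in part from size, for which no baseline was computed. The number of XMU-MP-1 p65 peaks, relative to vehicle p65 peaks in the same spans, was 11.6% at single TEAD peaks, 14.8% in clusters of 2 to 4 and 23.4% in clusters of 5 or more. These ratios were not adjusted for the strength of the p65 peaks. TEAD peaks with p65 in both the vehicle and XMU-MP-1 lists (1202 peaks) had a median TEAD fold of 10.0, those with p65 in the vehicle list alone (6883) 6.91, those with p65 in the XMU-MP-1 list alone (32) 15.6, and those with neither (15343) 5.92.

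A region on chromosome 1 from 228745877 to 228782058 held 17 TEAD, 18 control, 16 vehicle, 17 siTEAD4-labelled and 16 XMU-MP-1 peaks. The median distance between neighbouring summits there was 2234 bp in the control, 2235 bp in the vehicle and 2236 bp in the XMU-MP-1 list. The distances ranged from 679 to 2257 bp in the control, 783 to 2321 bp in the siTEAD4-labelled, 2195 to 2273 bp in the vehicle, 671 to 3877 bp in the XMU-MP-1 and 2161 to 2318 bp in the TEAD list. Without this region, the clusters of 5 or more TEAD peaks held 22.3% as many XMU-MP-1 as vehicle p65 peaks. A cluster of 16 TEAD peaks on chromosome 1 from 161389371 to 161440374 held no p65 peak in any list. The vehicle list had 1 mitochondrial peak of 16480 bp and the TEAD list 1 of 212 bp. The implied local background of peaks, relative to the list median, was 1.297 to 1.46 on chromosome 8 and 1.21 to 1.25 on chromosome 7 across the 5 lists. It was 0.532 to 0.609 on chromosome 13 and 0.564 to 0.667 on chromosome X.

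Both treated p65 lists were far shorter than their references. Lower sequencing depth is argued against: the depth on which peaks were called was 1.81 times the control for the list labelled siTEAD4 and 1.25 times the vehicle for XMU-MP-1, and 1.06 and 1.597 times before scaling. One common reduction of enrichment at all sites was first tested by the chance that a kept peak had the higher fold than a lost one, 0.861 for control and 0.863 for vehicle peaks, which lay between the bounds of 0.7 and 0.9 and decided nothing. Among peaks of both reference lists at equal −log10 q, sites with a TEAD peak were kept more often. The difference was 10.4 points (9.40 to 11.3) in the list labelled siTEAD4 and 11.8 points (10.8 to 12.7) with XMU-MP-1. The unmeasured difference in strength was read from the reference lists. It was 0.0102 (0.00113 to 0.0189) and 0.00725 (0.00102 to 0.0139) times what a common reduction would need to give these differences. At peaks called in both reference lists, this argues against a common reduction as the whole cause. Peaks of 1 reference list alone were not covered. Without either treatment, control peaks with a TEAD peak also had a vehicle peak more often at equal fold, by 8.28 points (7.11 to 9.44). Over the whole lists a common reduction therefore stays open. A lower yield at some kinds of site, differences between cultures or antibody lots, and an effect of the treatments on p65 stay open as possible explanations, since each condition has 1 library.

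Sites with a TEAD peak kept p65 more often, in the list labelled siTEAD4 as well as with XMU-MP-1. The strength of the p65 peak was tested as the cause. At equal fold the difference was 10.6 and 10.1 points. It was also 8.28 points (7.11 to 9.44) between the control and vehicle lists, so equal fold alone cannot exclude strength. Among peaks called in both of these lists, it was 10.4 and 11.8 points at equal −log10 q. The unmeasured difference in strength there was 0.0102 and 0.00725 times what these differences would need. At those peaks, this argues against strength as the whole cause. Over the whole lists strength stays open. Local background was 1.32 times as high at control peaks with a TEAD peak as at those without, and 1.098 times at vehicle peaks; the first of these ratios lay between the bounds first set, 1.1 and 1.5, so the test was replaced. At equal deciles of −log10 q alone, over all control and all vehicle peaks, the differences were 9.22 and 9.17 points. Within classes of equal −log10 q and equal background they were 8.38 points (7.57 to 9.19) and 8.65 points (7.95 to 9.36). This argues against local background as the cause. A candidate explanation that was not tested is that TEAD peaks mark open chromatin, where any antibody may enrich DNA; accessibility, a control antibody and TEAD without XMU-MP-1 were not analysed here.

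The treated lists shared 1175 of the sites common to control and vehicle, against 217 for independent lists. Strength was tested first in classes of control fold, where the observed number was 2.03 times the expected. In classes of −log10 q read in both reference lists it was 1.68 times. Both lie above the bound of 1.5, in a test written after the result was seen. This argues against measured strength as the whole cause, although it raised the expected number to 580 and 701. Strength that these readings miss was not tested here and stays open. A library deposited under both labels is argued against by unscaled summit pileups, which do not depend on the input. They were in the median ratio to within 10% at 33.6% (31.0 to 36.3) of 1196 overlapping peaks of the treated lists. The bound for 1 library was 90%. Between control and vehicle the share was 35.3% (34.5 to 36.2). It was lower between each treated list and its reference: 19.3% (17.5 to 21.2) for the list labelled siTEAD4 and 18.5% (16.7 to 20.5) for XMU-MP-1. A first test, on identical start, end and fold (0% of peaks), was dropped because these depend on the input. The peaks do not settle whether the list labelled siTEAD4 comes from siTEAD4 cells, given the name p65_Vert in its identifiers. An effect common to both treatments and sites enriched in every library stay open as untested explanations.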
